A study of Mus musculus with 6 samples.

How the data were processed

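RNA from mouse LT-HSCs was made into libraries with a TruSeq RNA kit after TRIZOL extraction, per the labels' protocols, which do not state the strand. The deposited values are whole-number counts per gene, not normalized, in 1 table of 47561 rows per library. The submitters' processing notes name bcl2fastq 2.19, cutadapt 1.16.5, HISAT2 2.1, featureCounts 1.6.4, DESeq2 2.11.40.6 and the build mm10, with no role, order or settings. Whether reads that map to several places were counted is not given in the sources used here. Each row carries a gene symbol, and 2046 rows have identifiers of the kind a transcript assembler gives, so part of the gene models may have been assembled from reads and the counts may derive from assembled coverage. Such a table of counts can move reads between overlapping genes and, with no stated strand, between a gene and its antisense partner.

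The symbols include 1465 names that start with LOC118, of which 1 is in the RefSeq table of GRCm38.p6, so the gene models appear to be later than that table. No coordinates are printed for this reason, and the table served only for names and neighbours. Of the tested symbols, 98.2% were in it. The genotype labels of KO replicates 2 and 3 name other Piezo numbers than the titles do, and the groups were taken from the titles, which all say Piezo1 KO.

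Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group, scaled by trimmed mean of M values (TMM), and tested with the quasi-likelihood F test of KO against control over all 6 libraries. Benjamini-Hochberg adjusted p-values under 0.05 passed. The SE of a log2 fold change was its absolute value divided by the square root of the F statistic. It was thus derived from the test and is not independent of it. CPM are counts scaled to the TMM-adjusted library total. The common biological coefficient of variation was 0.755. The floor for a count of 0 was 3 counts per library, between 0.0440 and 0.0539 CPM, and such floors cover counting error only. No pair of libraries agreed within sampling noise: the chi-square per gene was at least 132, where sampling noise alone gives about 1.

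Gene lists fixed before the data were examined, 34 in all, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, two-sided, and adjusted over the 32 lists with at least 5 tested members. The T and NK lineage list (4 tested members) and the bone marrow stroma list (3) were left out of the tests. The test was repeated with the correlation estimated from the data. The preset value takes members of a list to be almost independent, and the estimated correlations reached 0.778. For cholesterol synthesis the estimate was -0.0095, under the preset value, yet the unadjusted camera p went from 0.000228 to 0.0150. The versions of the test thus differ in more than the correlation, and a lost call need not come from correlated members. Fry was run as a test of each list alone: the lowest adjusted p was 0.146 for a shift in one direction, and 10 lists passed 0.05 for change in either direction. These were not the same lists as those called by camera. The lymphoid-primed progenitor, immediate early, actin and NF-kB lists passed in fry only. The antigen presentation, oxidative phosphorylation, ribosome biogenesis and stress response lists were called by camera only, with fry adjusted p-values of 0.0710, 0.457, 0.0526 and 0.106.

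Named genes followed a rule fixed before the data were examined: Piezo1, the 10 genes with the largest rise and the 10 with the largest fall past the threshold, with at least 5 CPM on average in the higher group and no overlap between groups, and up to 4 members with the smallest p of each described list. Symbols of the Gm, Rik, Ensembl and clone kinds were left out. As no gene passed, all 20 places were filled by the smallest unadjusted p, and each such gene is named as not past the threshold. The result of 1 of these genes is not reported here. Sex-linked genes and abundant markers of other cell types served as library checks.

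The same steps were tested on counts simulated from the means, dispersions and library sizes of these libraries, for 16022 genes of the comparison of KO with control. Of 50 genes changed per fold size, 8 were recovered at 2-fold, 31 at 4-fold, 41 at 8-fold and 48 at 16-fold, with 6 unchanged genes called. The changed genes and the members of the simulated lists were drawn from genes averaging at least 5 CPM, so recovery at lower expression was not tested. A list of 20 genes raised 2-fold was called and 0 of 20 unchanged lists were. Simulated genes were independent of each other, so the simulation does not test the effect of correlation between genes on list calls.

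The alternatives set before the data were examined were other size factors, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out, other thresholds and 1 surrogate variable from sva 3.50.0. Alternatives added after seeing the data removed the trend of each library on transcript length and GC content (longest GENCODE M21 transcript, 91.1% of tested genes, loess span 0.4), left out globin, granulocyte and immunoglobulin genes, used robust quasi-likelihood dispersions or weighted the libraries.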

Results

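RNA was sequenced from long-term hematopoietic stem cells (LT-HSCs), the bone marrow cells that renew themselves and give rise to all blood lineages. The cells had been sorted from control mice and from mice labelled as knocked out (KO) for Piezo1, the gene of a calcium-permeable channel opened by mechanical force. Each group held 3 libraries, and the comparison asks which transcripts differ in LT-HSCs of KO mice. Total counts lay between 59435258 (KO replicate 2) and 64653956 (control replicate 2), and between 16264 and 18540 genes had at least 1 count in a library. The labels do not state that the libraries came from separate mice, so the p-values measure only the spread between these samples, which may be technical.

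Piezo1 itself averaged 16.1 ± 8.66 CPM (counts scaled to the library total; SD, n = 3) in control and 7.24 ± 2.67 CPM (SD, n = 3) in KO libraries. The control libraries held 17.0, 7.02 and 24.3 CPM and the KO libraries 4.28, 7.99 and 9.46 CPM. The library labelled control replicate 2 thus lay below KO replicates 2 and 3, and every KO library still held at least 255 Piezo1 counts. The log2 fold change of KO over control was -1.15 (SE 0.56) with an edgeR quasi-likelihood adjusted p = 0.508, so the difference did not pass the threshold. Without control replicate 3 the log2 fold change was -0.73, and after the trends on transcript length and GC content were removed it was -2.16, or -2.41 with an uncentred version of that correction. No alternative passed the threshold (lowest adjusted p 0.302). The labels do not say which part of the gene was deleted, and counts over the whole gene can miss a deletion of part of it. Groups are therefore named as labelled throughout, and every direction that includes the library labelled control replicate 2 rests on its label.

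No single gene passed the adjusted threshold in edgeR. The genes below were named by the smallest unadjusted p in each direction, among genes with no overlap between the groups. The KO libraries averaged 1725 ± 360 CPM of Pf4, platelet factor 4, against 706 ± 123 CPM in control (SD, n = 3 each). Itga2b, the platelet integrin subunit CD41, averaged 116 ± 28.3 against 37.8 ± 9.11 CPM, and Fli1, a transcription factor of megakaryocytes, 194 ± 30.5 against 96.2 ± 1.77 CPM. The linker histone gene H1f4 averaged 90.6 ± 2.62 against 40.0 ± 0.204 CPM, and Egr1, an immediate early transcription factor, 74.7 ± 19.7 against 20.7 ± 2.73 CPM.

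The other genes named as higher in KO were Rsf1, which encodes a chromatin remodelling factor, the protease inhibitor gene Serpine2, Mvb12b of the endosomal sorting machinery, and Spn, the leukocyte surface sialoglycoprotein CD43. The log2 fold changes were 1.38 (SE 0.22) for Rsf1, 1.44 (SE 0.23) for Serpine2 and 0.97 (SE 0.17) for Spn, and Mvb12b averaged 59.9 ± 8.47 against 19.7 ± 5.24 CPM. As the naming rule required, the 3 KO libraries lay above the 3 control libraries in each of these genes named as higher. In edgeR's quasi-likelihood test each had an adjusted p = 0.255.

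On the lower side, Dnaja1, a co-chaperone of Hsp70 proteins, averaged 223 ± 14.3 CPM in KO against 418 ± 43.2 CPM in control (SD, n = 3 each). The interferon-inducible genes Rtp4 and Igtp averaged 66.1 ± 5.11 against 124 ± 5.37 CPM and 60.2 ± 14.0 against 154 ± 32.3 CPM. Jam3, a junctional adhesion molecule found on hematopoietic stem cells, averaged 5.86 ± 2.01 against 27.2 ± 6.58 CPM. Fastkd2, a mitochondrial RNA-binding protein gene, had a log2 fold change of -1.03 (SE 0.17), Surf2 -1.21 (SE 0.21), the glycosylation enzyme gene Alg3 -1.57 (SE 0.28) and the kinase gene Map3k1 -1.16 (SE 0.21). All 8 had an edgeR adjusted p = 0.255, not past the threshold.

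Ugt1a7c and Ifi208 had 0 counts in all 3 KO libraries. Ugt1a7c averaged 20.4 ± 3.15 CPM in control, at least 412-fold higher than a floor of 3 counts per library in KO, and Ifi208 averaged 6.07 ± 4.19 CPM, at least 123-fold higher. The control libraries held 10.8, 2.95 and 4.42 CPM of Ifi208, and without control replicate 1 its bound was 74.5-fold. Their edgeR adjusted p-values were 0.172 and 0.255, and the bounds cover counting error only. Ugt1a7c shares its last exons with the other Ugt1a genes, and the summed Ugt1a counts were 16.9, 23.1 and 22.9 CPM in the control and 3.40, 4.67 and 7.06 CPM in the KO libraries, where Ugt1a6a was counted in every library. Ifi208 belongs to a family of similar genes, of which Ifi213 and Ifi203 were looked at outside the naming rule. Ifi213 also had 0 counts in all 3 KO libraries, against 18.4, 3.14 and 1.96 CPM in control. Ifi203 overlapped, with 149, 126 and 102 CPM in control and 106, 144 and 138 CPM in KO. The values of Ugt1a7c and Ifi208 are uncertain where reads were split between copies.

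**Figure D1:**
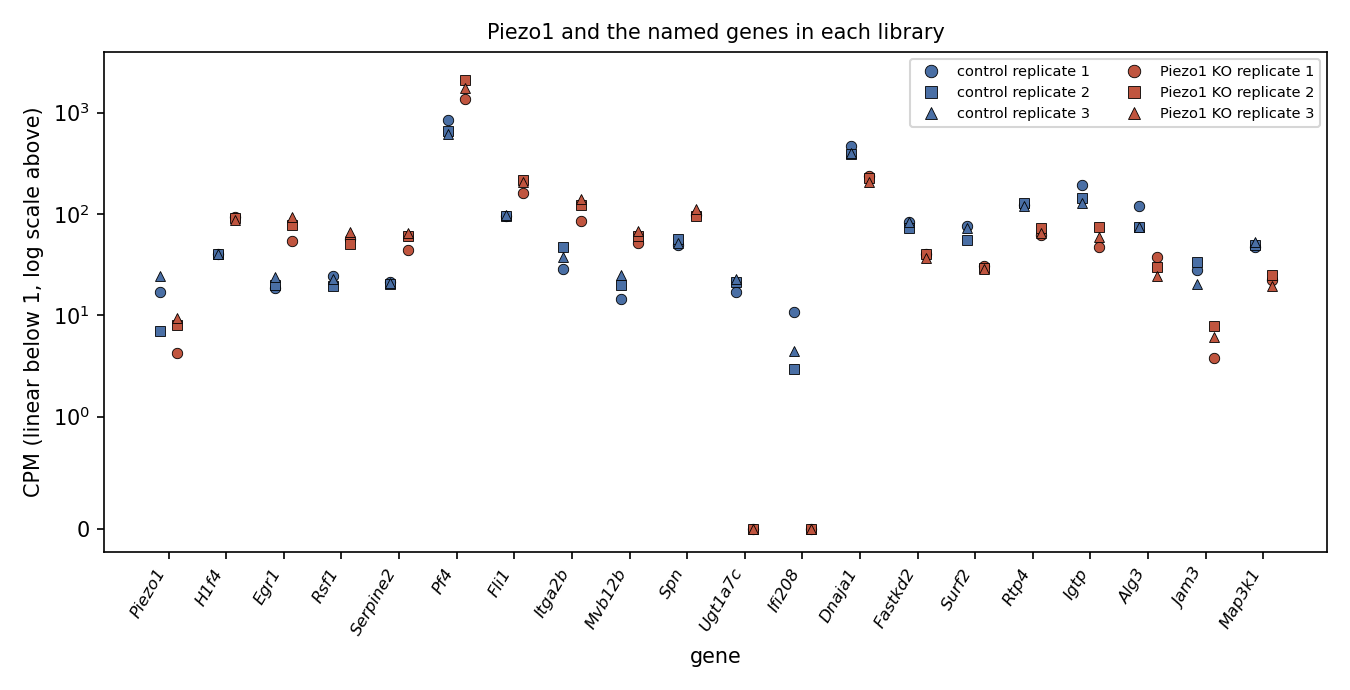
CPM (vertical axis, linear below 1 and logarithmic above) of Piezo1 and the genes named as higher or lower (horizontal axis), with 1 point per library, coloured by group and shaped by replicate number. Piezo1 overlaps between the groups, with control replicate 2 at 7.02 CPM. Each of the other genes was chosen from those that separate the groups, H1f4 for example at 40.0 against 90.6 CPM on average.

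Of 16022 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 lower in KO at an adjusted p under 0.05, with a lowest adjusted p of 0.172. At an unadjusted p under 0.05 there were 871 higher and 896 lower genes. Without KO replicate 3 these counts were 562 and 584, without control replicate 3 there were 1339 higher and without control replicate 1 there were 573 lower. After correction for transcript length and GC content the counts were 755 and 898. With an uncentred version of that correction, which moved the median of all genes to -0.15, they were 416 and 1338. Globin transcripts made up 0.741% to 2.43% of the counts in KO and 0.0274% to 0.352% in control libraries. The groups did not overlap in 3126 genes, 19.5% of those tested, where chance gives 10%. DESeq2 called 231 genes higher and 270 lower, including the 20 genes chosen by the smallest p, while limma-voom called 0, with 1209 higher and 1022 lower at an unadjusted p under 0.05.

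Megakaryocyte and platelet genes were called higher in KO as a list by camera with a preset correlation (adjusted p = 2.25e-05), a call lost with an estimated correlation (adjusted p = 0.713). Of 16 tested members, 15 had a positive log2 fold change, and the median was 0.90. At an unadjusted p under 0.05, 9 members were higher and 0 lower, and 7 were higher when adjusted over the list alone, against 0 over all genes tested. Such counts of members, here and for the lists below, are from edgeR unless DESeq2 is named. DESeq2 called 7 members of this list higher over all genes tested. Beside Pf4, Fli1 and Itga2b, the integrin subunit gene Itgb3 had a log2 fold change of 1.45 (SE 0.28). With the preset correlation the alternatives gave 4.35e-07 to 0.00829. Control replicate 3, which also held granulocyte transcripts, had the lowest mean over the list, at -1.19 (log2, relative to each gene's mean over the libraries).

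Interferon response genes were called lower in KO as a list. Their median log2 fold change was -0.79 over 35 members, 28 of them negative, with a camera adjusted p = 6.69e-06, and adjusted p = 0.713 with an estimated correlation. With the preset correlation the alternatives gave 2.77e-07 to 0.00136. At an unadjusted p under 0.05, 13 members were lower and 0 higher, and 4 were lower when adjusted over the list alone, against 0 over all genes tested. These 4 were Rtp4, Igtp, Gbp3 and Irgm1. Gbp3, an interferon-inducible GTPase gene, averaged 18.3 ± 2.55 CPM in KO and 42.2 ± 3.31 CPM in control, and Irgm1, another such gene, 65.0 ± 5.38 and 190 ± 89.2 CPM (SD, n = 3 each).

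Antigen presentation genes, of MHC class II and class I, were also called lower as a list, with all 10 members negative, a median of -0.76, a camera adjusted p = 0.00176, and adjusted p = 0.713 with an estimated correlation. With the preset correlation the alternatives gave 8.81e-05 to 0.0313. The class II gene H2-Aa had a log2 fold change of -1.40 (SE 0.29) and was the 1 member lower when adjusted over the list alone, against 0 over all genes tested. The class II genes H2-Eb1 and H2-Ab1 had log2 fold changes of -1.41 (SE 0.51) and -0.88 (SE 0.35), and the class I gene H2-K1 -0.64 (SE 0.19). In both the interferon and the antigen presentation lists, the mean over members overlapped between the groups.

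Genes of G2/M and mitosis were called higher in KO as a list, with 26 of 30 members positive and a median log2 fold change of 0.36. The camera adjusted p was 0.00169, and the adjusted p was 0.713 with an estimated correlation. Of these members, 12 were higher and 0 lower at an unadjusted p under 0.05, and Tpx2 and Top2a were higher when adjusted over the list alone, against 0 over all genes tested. Top2a, DNA topoisomerase II alpha, averaged 264 ± 19.5 CPM in KO and 156 ± 20.6 CPM in control (SD, n = 3 each), Tpx2, a spindle assembly factor gene, 92.7 ± 11.9 and 47.1 ± 8.23 CPM, and the proliferation marker gene Mki67 272 ± 32.2 and 128 ± 53.3 CPM. Cenpe, a kinetochore motor gene, had a log2 fold change of 0.78 (SE 0.24). The adjusted p was 0.0629 without control replicate 2 and 0.0533 without KO replicate 1, and 2.70e-05 to 0.0629 over all alternatives with the preset correlation.

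Cholesterol synthesis genes were called lower in KO as a list, with 18 of 24 members negative, a median log2 fold change of -0.56, a camera adjusted p = 0.00176, and adjusted p = 0.480 with an estimated correlation. That estimate was -0.0095, under the preset value, so a higher correlation was not why this call was lost. With the preset correlation the alternatives gave 0.000513 to 0.0141. At an unadjusted p under 0.05, 10 members were lower and 1 higher, and in edgeR 0 passed when adjusted over the list alone or over all genes tested. DESeq2 called 3 members lower over all genes tested. Fdft1, squalene synthase, averaged 19.6 ± 5.07 CPM in KO and 56.9 ± 28.8 CPM in control (SD, n = 3 each). The pathway genes Sc5d, Msmo1 and Hmgcs1 had log2 fold changes of -0.93 (SE 0.24), -0.96 (SE 0.27) and -1.03 (SE 0.33).

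Adhesion receptor and focal adhesion genes were called higher in KO as a list, with 27 of 35 members positive, a median log2 fold change of 0.50, a camera adjusted p = 0.0207, and adjusted p = 0.713 with an estimated correlation. The mean over the list (log2, relative to each gene's mean over the libraries) was 0.34 in control replicate 2, inside the KO range of 0.17 to 0.35, and -0.67 and -0.53 in control replicates 1 and 3, which stood apart from the other libraries. Without control replicate 1 the median was 0.31. Adjusted over the list alone, Itga6, Itgb3 and Zyx were higher and Jam3 was lower, against 0 over all genes tested. The integrin gene Itga6 averaged 140 ± 28.0 CPM in KO against 71.0 ± 19.6 CPM in control (SD, n = 3 each), and Zyx, the focal adhesion protein zyxin, 145 ± 28.6 against 86.0 ± 1.67 CPM. The adjusted p was 0.0683, 0.238, 0.0533 and 0.130 without control replicate 1, control replicate 3, KO replicate 1 and KO replicate 3, 0.132 after the trends on transcript length and GC content were removed, and 0.259 with 1 surrogate variable, in a range of 0.00797 to 0.259 over all alternatives with the preset correlation.

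Nuclear-encoded oxidative phosphorylation genes, ribosome biogenesis and Myc target genes, unfolded protein and integrated stress response genes, and iron and redox genes were called lower in KO with smaller shifts. Their median log2 fold changes were -0.16, -0.23, -0.36 and -0.16, with camera adjusted p-values of 0.0207, 0.0337, 0.0334 and 0.0406. With an estimated correlation the adjusted p-values were 0.764, 0.713, 0.713 and 0.713. At an unadjusted p under 0.05, 3 of 40, 7 of 24, 3 of 20 and 4 of 21 members were lower, and 0, 0, 0 and 1 were higher. Adjusted over the list alone, only Nfe2l2 was lower among these 4 lists, against 0 over all genes tested. Nfe2l2, the transcription factor of the antioxidant response, averaged 80.3 ± 6.36 CPM in KO and 141 ± 3.71 CPM in control (SD, n = 3 each).

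Within these lists, the spermidine synthase gene Srm averaged 221 ± 68.7 CPM in KO and 433 ± 24.4 CPM in control, and Nop56, a nucleolar protein gene, 270 ± 23.3 and 438 ± 77.2 CPM (SD, n = 3 each). The endoplasmic reticulum chaperone gene Hspa5 averaged 231 ± 17.7 and 396 ± 95.3 CPM, Xbp1 89.1 ± 7.25 and 152 ± 34.2 CPM, and Uqcrc1 of respiratory complex III 363 ± 90.6 and 596 ± 66.6 CPM. Gclc, an enzyme gene of glutathione synthesis, went the other way, with 59.9 ± 2.54 against 30.4 ± 10.7 CPM. The log2 fold changes of Dkc1, Nop58, Sdhd, Atp5c1, Ndufa9, Cat and Ftl1 were -0.57, -0.50, -0.57, -0.45, -0.40, -0.82 and -0.48, and those of Herpud1 and Sdf2l1 were -0.76 and -0.83.

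In all 4 lists the mean over members overlapped between the groups, and for oxidative phosphorylation it was -0.15 in control replicate 2, inside the KO range of -0.18 to 0.041, and 0.11 and 0.27 in control replicates 1 and 3. Some medians also moved with 1 library left out. That of oxidative phosphorylation was -0.28, -0.018 and -0.088 without control replicate 2, control replicate 3 and KO replicate 3, and that of iron and redox -0.33, -0.31 and -0.44 without control replicate 1, control replicate 2 and KO replicate 1. The ribosome biogenesis median was -0.36 without KO replicate 1 and the stress response median -0.21 without KO replicate 3. Each of these 4 calls was lost without any 1 of several libraries. The oxidative phosphorylation adjusted p was 0.0683, 0.374, 0.0640 and 0.122 without control replicate 1, control replicate 3, KO replicate 2 and KO replicate 3, and the iron and redox value 0.0944, 0.262, 0.142 and 0.156 without the same libraries. The stress response value was 0.0568, 0.111, 0.0878 and 0.122 without control replicate 1, control replicate 2, KO replicate 2 and KO replicate 3. The ribosome biogenesis value was 0.0511, 0.152 and 0.266 without control replicate 2, control replicate 3 and KO replicate 2. After the trends on transcript length and GC content were removed, the oxidative phosphorylation, stress response and iron lists had adjusted p-values of 0.580, 0.245 and 0.119, and with 1 surrogate variable 0.277, 0.259 and 0.322. The ribosome biogenesis value was 0.0511 with a filter of 5 CPM in 3 libraries. With the replicate number as a block, the ribosome biogenesis and iron values were 0.0501 and 0.0766. Over all alternatives with the preset correlation the values ranged from 0.000254 to 0.580, 0.00417 to 0.266, 0.00858 to 0.259 and 0.00834 to 0.322 for oxidative phosphorylation, ribosome biogenesis, stress response and iron.

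**Figure D2:**
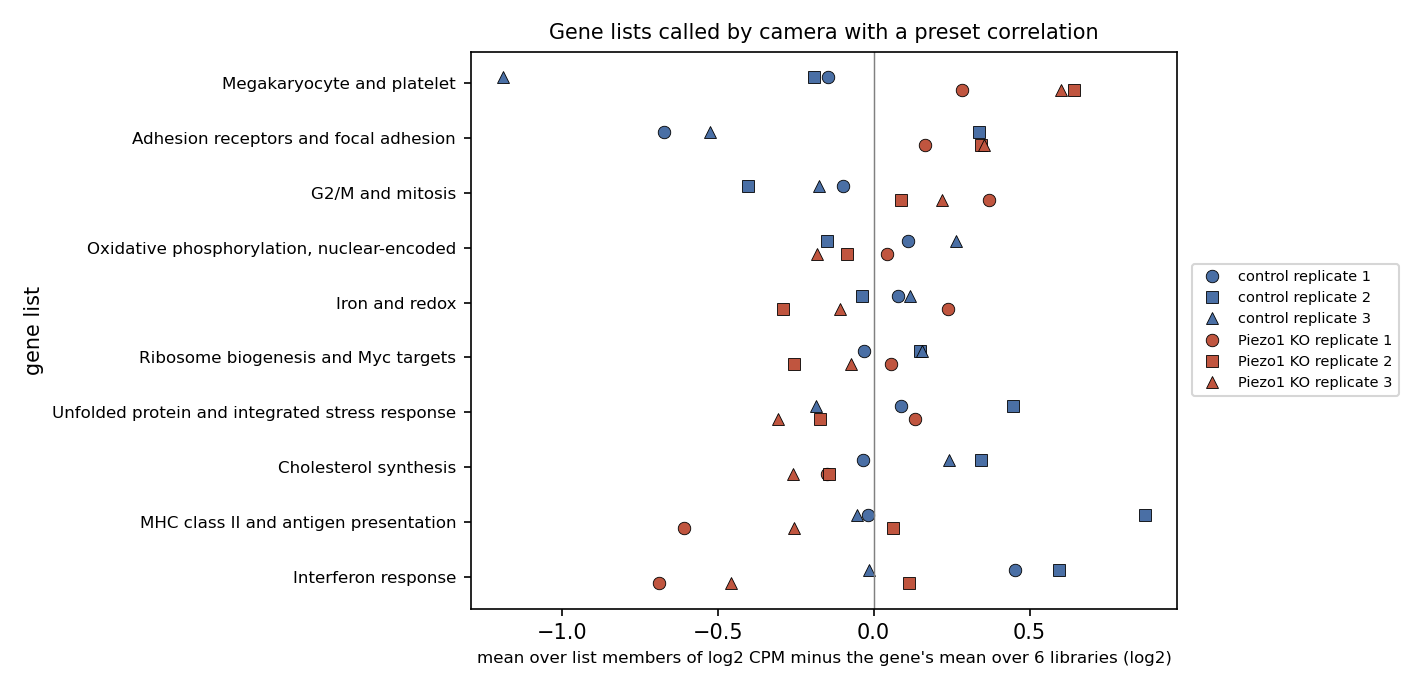
Mean over the members of each called gene list (vertical axis) of log2 CPM minus each gene's mean over the 6 libraries (horizontal axis, log2), with 1 point per library, coloured by group and shaped by replicate number. In 3 of the 10 lists, Megakaryocyte and platelet, G2/M and mitosis, and Cholesterol synthesis, the libraries of the groups do not overlap, and in the other 7 they do. Of all 32 tested lists, 6 do not overlap, among them the lymphoid-primed progenitor, endothelial and actin lists, which were not called.

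Genes of stem cell identity were not called as a group. The list had a median log2 fold change of 0.06 over 30 members and a camera adjusted p = 0.837, with 2 members higher and 3 lower at an unadjusted p under 0.05. Ly6a, the stem cell antigen Sca-1, averaged 123 ± 72.9 CPM in KO and 327 ± 44.7 CPM in control, and Procr, the surface receptor EPCR, 13.8 ± 11.4 and 48.7 ± 23.2 CPM (SD, n = 3 each). Gfi1b, a transcriptional repressor gene, had a log2 fold change of -0.73 (SE 0.20) and Ptpn21 2.36 (SE 0.58). None of the 4 passed the adjusted threshold in edgeR, while DESeq2 called Ly6a and Gfi1b lower and Ptpn21 higher.

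Mechanosensitive and calcium channel genes and the calcium response genes were not called either, with camera adjusted p-values of 0.433 and 0.171. Beside Piezo1, the channel genes with the smallest p were P2rx4, Orai3 and Cacnb2, with log2 fold changes of -0.96 (SE 0.36), -0.97 (SE 0.38) and 1.03 (SE 0.50). In the calcium response list, Camkk2, a calmodulin-dependent kinase kinase gene, had a log2 fold change of 1.42 (SE 0.42). Atp2b4, S100a6 and Cast had log2 fold changes of 0.67, -0.57 and 0.60. That of Atp2b4 was 0.076 with the correction for length and GC content and -0.091 with its uncentred version.

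Immediate early and heat shock genes, which also respond to cell handling, were not called as a list (camera adjusted p = 0.575). Of 22 tested members, 16 had a positive log2 fold change and 6 a negative one, with a median of 0.72. The fry test for change in either direction gave an adjusted p = 0.00715. Adjusted over the list alone, Egr1 was higher and the chaperone genes Hspa8, Dnaja1 and Dnajb1 were lower, against 0 over all genes tested. Hspa8 averaged 1437 ± 113 CPM in KO and 3129 ± 850 CPM in control (SD, n = 3 each), and Dnajb1 70.8 ± 5.29 and 111 ± 12.3 CPM.

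Control replicates 1 and 3 stood apart from the other libraries, control replicate 1 at -187 on the first principal component (32.6% of the variance; the others from -0.781 to 83.6) and control replicate 3 at -166 on the second (23.4%; the others from 24.7 to 45.2). Transcripts of other cell types also differed between libraries. The 4 adult globin genes had log2 fold changes between 2.80 and 3.08, all with the KO libraries above the control libraries. Hbb-bs held 77.8, 338 and 1019 CPM in control and 6835, 2606 and 2676 CPM in KO. The other 17 erythroid genes had a median log2 fold change of 0.05, and the list of 21 was not called (camera adjusted p = 0.629). The red cell genes Alas2 and Slc4a1 reached 58.1 and 23.9 CPM in KO replicate 1 but 3.45 and 0.673 CPM in KO replicate 3, against at most 13.3 and 2.46 CPM in control. The globin copies are near-identical, and the split of reads between them is uncertain. Hbb-bs, Hbb-bt, Hba-a2 and Car2, with log2 fold changes of 3.08, 2.93, 2.89 and -0.68, had edgeR adjusted p-values of 0.311, 0.277, 0.386 and 0.397.

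Control replicate 3 held granulocyte and plasma cell transcripts at levels seen in no other library. S100a8 reached 4466 CPM there and at most 485 CPM elsewhere, Ngp 2021 against at most 140 CPM, the immunoglobulin gene Igkc 2517 against at most 1.84 CPM, and Jchain 633 CPM against 0 counts. In total, 12 granulocyte genes took 1.18% and 3 immunoglobulin genes 0.401% of its counts. The granulocyte list was not called (median log2 fold change -2.74, camera adjusted p = 0.171), but it was called lower without control replicate 1, control replicate 2, KO replicate 2 or KO replicate 3 (adjusted p of 0.000913, 0.0108, 0.0124 and 0.00930). It was also called with no filter, with 1 surrogate variable and with the replicate number as a block, in a range of 0.000913 to 0.902 over all alternatives with the preset correlation. The value of 0.902 was that without control replicate 3. Of its members, Retnlg, Lyz2, Cd177 and Ngp had log2 fold changes of -7.96, -0.85, -5.14 and -3.63, and without control replicate 3 those of Cd177 and Ngp were 0.17 and 2.50. In all 6 libraries the Y-linked genes Ddx3y and Eif2s3y were at 55.2 CPM or more, and Xist was at most 1.73 CPM.

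**Figure D3:**
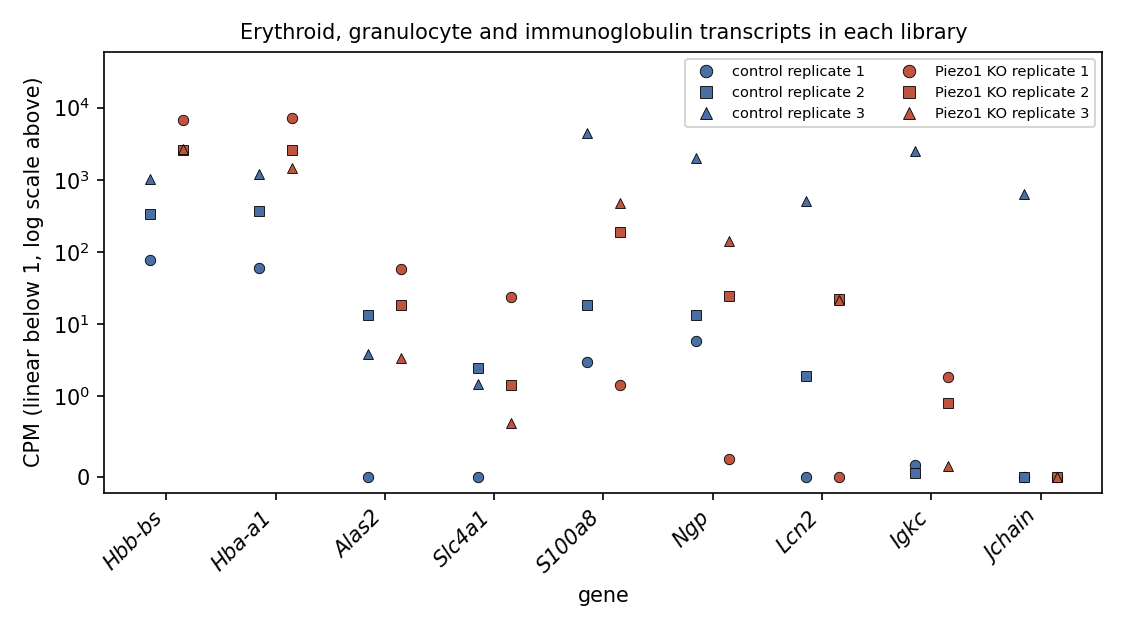
CPM (vertical axis, linear below 1 and logarithmic above) of erythroid, granulocyte and immunoglobulin genes (horizontal axis), with 1 point per library, coloured by group and shaped by replicate number. Both globin genes are higher in the 3 KO libraries, and S100a8, Ngp, Lcn2, Igkc and Jchain are highest in control replicate 3, S100a8 at 4466 CPM.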

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

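The alternatives on length and GC, foreign transcripts, robust dispersions and library weights, and the fold bounds and list medians with 1 library left out, were chosen after seeing the data, and the others before. Counts of genes past adjusted p 0.05 were 0 higher and 0 lower in edgeR. DESeq2 gave 231 higher and 270 lower, the filter of 5 CPM in 3 libraries gave 1 lower (Ugt1a7c), and leaving out 1 library gave 0 to 1 higher and 0 lower. The 1 higher gene, without control replicate 1, was Gm20716, at 154 CPM in control replicate 1 and 0 in the other controls (named after its values were seen). The cause of the higher DESeq2 count was not tested. Unadjusted counts were 871 higher and 896 lower, 379 and 319 with 1 surrogate variable, and from 562 to 1339 higher and 573 to 1299 lower with 1 library left out. The Piezo1 log2 fold change stayed negative and short of the threshold in every alternative, from -2.41 (uncentred length and GC offset) to -0.73 (without control replicate 3). Gene lists called were 10, from 7 to 10 with 1 library left out, 7 with the length and GC offset, and 0 with an estimated correlation. Without control replicate 3 and with the offset there were 6. An uncentred version of that offset, run first and replaced because it moved the median of all genes to -0.15, also called 6. TMM, RLE, total-count scaling and the centred offset kept that median between 0.00 and 0.08. The replicate block called 9 lists, adding granulocytes and losing ribosome biogenesis and iron, and 0 genes. Same-numbered libraries deviated together with correlations of 0.0380, 0.0160 and 0.0333, under 0.1 but the highest for each library. With 3 libraries per group such a match can arise by chance, so it neither shows nor excludes a pairing. Over 74 genes chosen by the naming rule and 1397 comparisons with an alternative, 1345 kept direction and side of the threshold, 49 passed it, and 3 turned. Of the 49 passes, 48 were in DESeq2 and 1 was with the stricter filter. The genes that turned were Atp2b4, Cd177 and Ngp. Atp2b4 was at -0.091 with the uncentred offset, which moved the median of all genes down, but at 0.076 with the centred one. Cd177 and Ngp were at 0.17 and 2.50 without control replicate 3 (-12.20 and -5.77 without KO replicate 3, and -33.12 and -6.71 with 1 surrogate variable). Cd177 had 0 counts in control replicate 1 and KO replicates 1 and 2, so its fitted values depend on near-zero counts. Ngp had 112467 counts in control replicate 3, 359 and 924 in control replicates 1 and 2, and 13, 1486 and 8738 in the KO libraries.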

Other observations

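The tests of transcript length, of control replicate 3, of histone genes and of the Piezo1 neighbourhood, and the split counts other than that of genes past the adjusted threshold, were chosen after the results were seen. Replication-dependent histone genes had higher values in KO across the family, though none passed the adjusted threshold in edgeR. Of 61 such genes tested, 60 had a positive log2 fold change, with a median of 0.85, 16 were higher and 0 lower at an unadjusted p under 0.05, and 37 did not overlap between groups, where chance gives 10% and all tested genes together gave 19.5%. These related genes were measured in the same libraries and are not independent replicates, so the counts do not measure chance. The linker histone genes H1f1 to H1f5 had log2 fold changes of 2.30, 1.87, 1.52, 1.18 and 1.11, and H1f0, whose transcript carries a poly(A) tail, 1.15. How reads of near-identical histone copies were split between them is uncertain here.

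The remaining fixed lists, 22 in all with those described above, were not called. The median log2 fold change was 0.47 for lymphoid-primed progenitor genes (camera adjusted p = 0.791), 0.48 for quiescence genes (0.114), 0.54 for YAP and Hippo targets (0.339), 0.54 for NF-kB genes (0.299), 0.26 for TGF-beta and BMP genes (0.295), 0.19 for mitochondrially encoded genes (0.495) and 0.07 for ribosomal proteins (0.791). It was -0.14 for glycolysis (0.318), -0.19 for fatty acid oxidation (0.253), -0.62 for B lineage (0.395) and -0.27 for endothelial genes (0.641). With the length and GC offset the median was 0.24 for quiescence genes, 0.17 for YAP and Hippo targets and -0.17 for TGF-beta and BMP genes. For ribosomal proteins and glycolysis it grew in size, to 0.22 and -0.26. Actin, p53 and monocyte genes had adjusted p-values of 0.855, 0.586 and 0.837. Their medians (-0.09, -0.07 and -0.23) and means (0.17, 0.06 and 0.03) differed in sign, and camera gave a negative direction for actin and p53 and a positive one for monocytes. The sex-linked list had 0.318 (median 0.46). The lists of T and NK lineage and of bone marrow stroma, with 4 and 3 genes that could be tested, had medians of -0.91 and 0.83 and no list test. Without 1 library, B lineage and NF-kB genes (0.0241 and 0.0481 without control replicate 2) and mitochondrially encoded and ribosomal protein genes (0.0470 and 0.0480 without control replicate 3) were called. Ribosomal proteins were also called with the length and GC offset (0.000698), and quiescence genes with the stricter filter (0.0372). In the main fit with an estimated correlation, which was 0.778 for ribosomal proteins, the camera adjusted p-values of ribosomal proteins and quiescence genes were 0.944 and 0.713. Over all alternatives with the preset correlation, these 5 lists ranged from 0.0241 to 0.955, 0.0481 to 0.882, 0.0470 to 0.881, 0.000698 to 0.976 and 0.0372 to 0.338.

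For the histone genes, a trend on transcript length and GC content is argued against as the whole cause, since their median was 0.83 once it was removed. More carry-over of RNA without a poly(A) tail into KO libraries could account for part of it: 4 other such RNAs (Rn7s1, Rn7s2, Rn7sk and Rpph1) had a median of 0.35 and reached 0.84, too few genes to decide. More cells in S phase also stays open, since the list of DNA replication and G1/S genes was not called (camera adjusted p = 0.433, median -0.13) and its members went both ways. An effect of the genotype is untested beyond the comparison itself.

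The 10 list calls were weighed against a trend on transcript length, since log2 fold change rose with transcript length across 7716 genes above 16 CPM (Spearman's rho = 0.369, genes not being independent replicates). The trend was uneven over libraries: the median log2 deviation of the longest quintile of genes minus the shortest was -0.54 and -0.24 in control replicates 1 and 3 and 0.46 in KO replicate 3, but 0.131 in control replicate 2, close to the 0.126 and 0.105 of KO replicates 1 and 2. With the trend removed, 6 calls stayed past the threshold in their direction, which argues against it as their whole cause: megakaryocyte (4.23e-06), G2/M (0.000111), interferon (3.72e-05), antigen presentation (0.00771), ribosome biogenesis (0.00417) and cholesterol (0.00123). For adhesion (0.132) and oxidative phosphorylation (0.580) the trend may account for the call, as the medians lost most of their size, from 0.50 (quartiles 0.05 and 0.90) to 0.19 (-0.03 and 0.73) and from -0.16 (-0.34 and -0.03) to -0.025 (-0.14 and 0.12). For the stress response (0.245, median -0.36 with quartiles -0.62 and 0.15 to -0.24 with -0.54 and 0.15) and iron lists (0.119, median -0.16 with -0.62 and -0.03 to -0.20 with -0.60 and 0.02), the first median kept most of its size and the second moved away from 0, so the question stays open, and in all 4 lists the move was smaller than the spread of members.

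Foreign cells in control replicate 3, where S100a8 reached 4466 and Igkc 2517 CPM, could also lie behind list calls, although a sort for LT-HSCs would remove granulocytes and plasma cells. Without that library, 6 calls held in direction: megakaryocyte (0.00829), G2/M (0.00541), interferon (3.05e-06), antigen presentation (0.00119), cholesterol (0.0141) and stress response (0.0141). The oxidative phosphorylation call was lost (0.374, median -0.16 to -0.018 with quartiles -0.37 and 0.22), which foreign cells could produce. It was also lost without control replicate 1, KO replicate 2 or KO replicate 3 (0.0683, 0.0640 and 0.122), which did not hold these transcripts at such levels. The calls of adhesion (0.238), ribosome biogenesis (0.152) and iron (0.262) were lost too, with medians of 0.36, -0.16 and -0.12. For all of these lists, fewer libraries and foreign cells cannot be told apart. Of 22 granulocyte genes in the list, 17 passed the expression filter, which does not show that LT-HSCs express them. Retnlg, for example, passed with 0.726, 0 and 141 CPM in control and 0, 0.565 and 0 CPM in KO libraries. No biological explanation for these transcripts in 1 control library was tested.

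With 3 libraries against 3 there are 10 splits, so the share of splits with as large a count cannot be under 0.1. The labelled split gave 1767 genes at an unadjusted p under 0.05, and the highest other split 728, so 1 of 10 splits was as large. DESeq2 called 501 genes in the labelled split and at most 70 in another (1 of 10), and edgeR called 0 past the adjusted threshold in all 10. Camera with the preset correlation called 10 lists in the labelled split, and another split also called 10, so 2 of 10 were as large.

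Within 10 Mb of Piezo1, 16 of 130 tested genes had an unadjusted p under 0.05, 12.3% (Fisher's exact test against all other tested genes, two-sided, p = 0.576).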
